A study of Homo sapiens with 4 samples.

How the data were processed

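Total RNA was measured in 4 libraries of A549 cells, an established human lung adenocarcinoma line that the series describes as NRF2-activated. Per the labels, 2 libraries came from cells transfected with control siRNA, 1 from cells transfected with CEBPB siRNA-1 and 1 from cells transfected with CEBPB siRNA-2. The medium was replaced 24 h after transfection and the cells were harvested after another 24 h. Libraries were strand-specific and were read as 76-base single-end reads. The CEBPB siRNA libraries came from separate transfections, since each had a different siRNA, and their spread includes the difference between the siRNAs. The labels do not say whether the control libraries came from separate cultures. The p-values thus measure only the spread between these samples, which may be technical between the controls.

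Per the submitters' processing notes, the tools named are STAR 2.7.0d, StringTie 2.1.4, HTSeq 0.13.5, DESeq2 1.26.0 and the genome build hg19, with no role or order. The deposited table holds 57820 genes, each with 1 value per library and the authors' own comparison. The file headers do not name the unit of the per-library values. It was taken as FPKM (fragments per kilobase of transcript, scaled to library depth) because the deposited headers are those of StringTie and because the columns sum to between 494066 and 528606, where TPM would give the same total in every library. As a check, 1949 genes with 1 basic transcript in GENCODE 29 were used to compute the reads that FPKM would imply. The median was 8959000 reads (quartiles 7773000 and 9494000), beside the 8341080 to which the authors' mean normalized counts sum. That sum is the depth per library as far as the table shows it. Counts per library were not used here. From the steps of low FPKM values the relative depth was 1 in control 1, 0.967 in control 2, 1.02 with siRNA-1 and 0.992 with siRNA-2.

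The remaining columns are a DESeq2 results table, per the file headers. The signal column is the authors' mean count after division by size factors. The log2 columns are the authors' log2 fold change of CEBPB siRNA over control and its standard error. The score is the authors' Wald statistic, and the p-value columns hold the authors' p-value and adjusted p-value. The direction of the fold change was read from its sign against the FPKM columns. Of 14675 genes with an adjusted p-value there, 607 were below 0.05. The authors' values are quoted as theirs and were not recomputed.

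The design written before the data were examined called for a count test and named the test to use if the table held normalized values. That test is limma (3.58.1, R 4.3.3) with an intensity trend on log2(FPKM + 1), over the 14068 genes with a mean of at least 1 FPKM over the 4 libraries, without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. It had 2 residual degrees of freedom and 3.61 from the prior. The residual spread pools the difference between the controls with the difference between the siRNAs. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene at 0 is described as listed at 0, and no fold is given against it. Among 9122 genes with an authors' mean count of at least 100, 1 gene was listed at 0 FPKM in a library. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot go below p = 0.333.

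The siRNAs were compared in a fit with 3 groups and a contrast of siRNA-1 minus siRNA-2. That fit has 1 residual degree of freedom, from the controls, and assumes that each siRNA library varies as the controls do. Agreement of the siRNAs was measured across genes against controls that the other siRNA did not use, and against both controls beside a simulation of unchanged groups (100 draws).

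The 30 gene lists were written for the re-analysis, not by the submitters. The lists were fixed beforehand, and 28 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, with fry, and with camera on the authors' Wald statistics. Of 567 listed symbols, 433 genes were tested. The genes named were CEBPB, up to 12 per direction with the largest log2 change past the threshold, both siRNA libraries beyond both controls and a mean of at least 5 FPKM, and up to 4 members per list past the threshold (or the member with the smallest p). Not every gene that met these rules is shown. Between the siRNAs, the 5 largest differences per direction were named. Other members and genes, including those named from the authors' deposited table, were chosen after their values were seen.

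The limma test was checked on simulated data with spreads drawn from its own prior. It recovered 4% of genes changed by 1 on the log2 scale, 72% of those lowered by 2, 79% of those raised by 2 and 96% of those raised by 3, with 4.3% false calls. Changes were placed only in genes averaging at least 5 FPKM, and both groups of a gene had the same spread. The rates thus do not cover lower genes or a larger spread between the siRNAs than between the controls. For the list test, 20 of 20 simulated lists of 20 genes shifted by 0.5 were found with the preset correlation and 17 with the estimated one. Unshifted lists were run with the preset correlation only, and 0 of 20 were found. The simulated genes varied independently, so this does not show how the preset correlation performs where members of a list vary together.

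Short words in 3' UTRs were related to library differences over 8431 genes with a mean of at least 5 FPKM and a GENCODE 29 3' UTR of at least 50 bases, matched by gene identifier and with no coordinate taken from that build. Length, GC content and expression were covariates (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). In simulated data, a word whose carriers were lowered by 0.2 ranked first in 20 of 20 draws. The noise there was the control difference in shuffled gene order, with a standard deviation of 0.350 against 0.554 between the siRNAs. Only words with many carriers were planted. The draws thus do not show how well rarer words, or words amid the larger spread between the siRNAs, would be found. Alternatives were the pseudocount, the filter, scaling, a replicate block, a 3-group fit, a minimum fold and leaving out each library. Count-based alternatives could not be run on FPKM.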

Results

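A549 is a lung adenocarcinoma line in which the transcription factor NRF2 is active, and the series asks which transcripts depend on CEBPB, a C/EBP family transcription factor, in these cells. Expression was measured in 2 control siRNA libraries and in 2 CEBPB knockdown libraries, 1 for each of 2 different siRNAs. The libraries listed 13752 to 14325 genes at 1 FPKM or more and summed to between 494066 and 528606 FPKM. The relative depth lay between 0.967 and 1.02 of that of control 1. Mitochondrially encoded genes made up 17.5% and 18.2% of FPKM in the controls, 16.9% with siRNA-1 and 14.4% with siRNA-2. Across the tested genes, log2 values correlated at 0.981 between the controls and 0.951 between the siRNA libraries. Correlations with the controls were 0.926 and 0.927 for siRNA-1, and 0.963 and 0.966 for siRNA-2. Genes are not independent replicates.

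The target itself, CEBPB (ENSG00000172216.4), was at 78.7 and 80.9 FPKM in the controls, 12.9 with siRNA-1 and 10.97 with siRNA-2. Its log2 change was -2.65 ± 0.17 (SE, n = 2 libraries per group), with a limma adjusted p of 0.0167. The authors' deposited table gives a log2 change of -2.76 with an adjusted p of 8.5e-24. In limma the call was lost without control 1 (adjusted p = 0.461) or without control 2 (adjusted p = 0.328), where the log2 changes were -2.67 and -2.63.

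LTB, which encodes the membrane cytokine lymphotoxin beta, rose from 0.980 and 0.842 FPKM to 34.7 with siRNA-1 and 28.99 with siRNA-2, a log2 change of 4.10 ± 0.20. The cytokine IL32 rose from 15.6 and 14.5 FPKM to 276 and 193, by 3.85 ± 0.22. CCL2, a monocyte-attracting chemokine, rose from 74.2 and 70.1 FPKM to 682 and 517, by 3.02 ± 0.19. The metallothionein MT2A went from 30.5 and 33.4 FPKM to 237 and 201, and the class I antigen HLA-B from 5.66 and 4.40 to 41.7 and 31.5. Their log2 changes were 2.74 ± 0.17 and 2.64 ± 0.22. KCNMA1, a calcium-activated potassium channel, increased by 2.52 ± 0.21, and EFHD2, a calcium-binding protein gene, by 2.16 ± 0.16. AKAP2 had a log2 change of 3.41 ± 0.26, but it overlaps PALM2-AKAP2, which was called lower (6.51 and 5.24 FPKM in the controls, listed at 0 with siRNA-1 and at 0.017 with siRNA-2). The authors' deposited table gives neither an adjusted p, and a mean normalized count of 0.488 for AKAP2, so reads may have been assigned to 1 locus or the other, and neither change is certain. HLA-B and MT2A also belong to families with near-identical members. Each of these 8 genes had a limma adjusted p between 0.0167 and 0.0275.

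SLC51B, a subunit of the bile acid and steroid exporter, was at 14.8 and 13.6 FPKM in the controls, listed at 0 with siRNA-1 and at 0.221 with siRNA-2. S100P, a calcium-binding protein gene, was at 9.25 and 17.2 FPKM in the controls, 0.317 with siRNA-1 and listed at 0 with siRNA-2. The airway mucin MUC5B fell from 124 and 128 FPKM to 17.1 and 25.01, a log2 change of -2.55 ± 0.22. AGR2, a disulfide isomerase needed for mucin folding, fell from 119 and 162 FPKM to 27.0 and 30.7, a log2 change of -2.23 ± 0.20. RBP4, the plasma retinol carrier, went from 11.5 and 14.2 FPKM to 1.31 and 1.47. HHIPL2 changed by -2.91 ± 0.20, AHCYL2 by -2.39 ± 0.21, and the neuropeptide Y receptor NPY1R by -2.37 ± 0.20. CYP4F3, a leukotriene and fatty acid hydroxylase, changed by -2.22 ± 0.22 and the aldo-keto reductase AKR1C1 by -2.18 ± 0.22. Limma adjusted p-values of these 10 genes lay between 0.0167 and 0.0376.

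In all, 9 genes were higher and 24 lower in limma, each with both siRNA libraries beyond both controls, and 1716 genes had an unadjusted p below 0.05 where chance gives 703. The libraries of the groups did not overlap for 3310 higher and 2950 lower genes, or 44.5%, where 4 libraries of equal spread would give 33.3% by chance. The siRNA libraries differed more from each other than the controls did (standard deviation 0.554 against 0.350). Such a spread raises the chance share without any shared effect, so the excess over 33.3% does not measure one. The authors' deposited table holds more calls, 398 higher and 209 lower. Of these, 568 were tested here, all with the same sign in FPKM, and 565 had non-overlapping libraries. Both tests use the same 4 libraries, so this match is not independent evidence. The tests shared 31 calls. The limma counts depend on the settings: no gene passed without control 1 (736 at an unadjusted p below 0.05), without control 2 (685) or with no expression filter (2438). They were 28 and 44 without siRNA-1, 870 and 894 without siRNA-2, 538 and 433 in the 3-group fit, and 5 and 5 for a fold of at least 1.5.

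**Figure D1:**
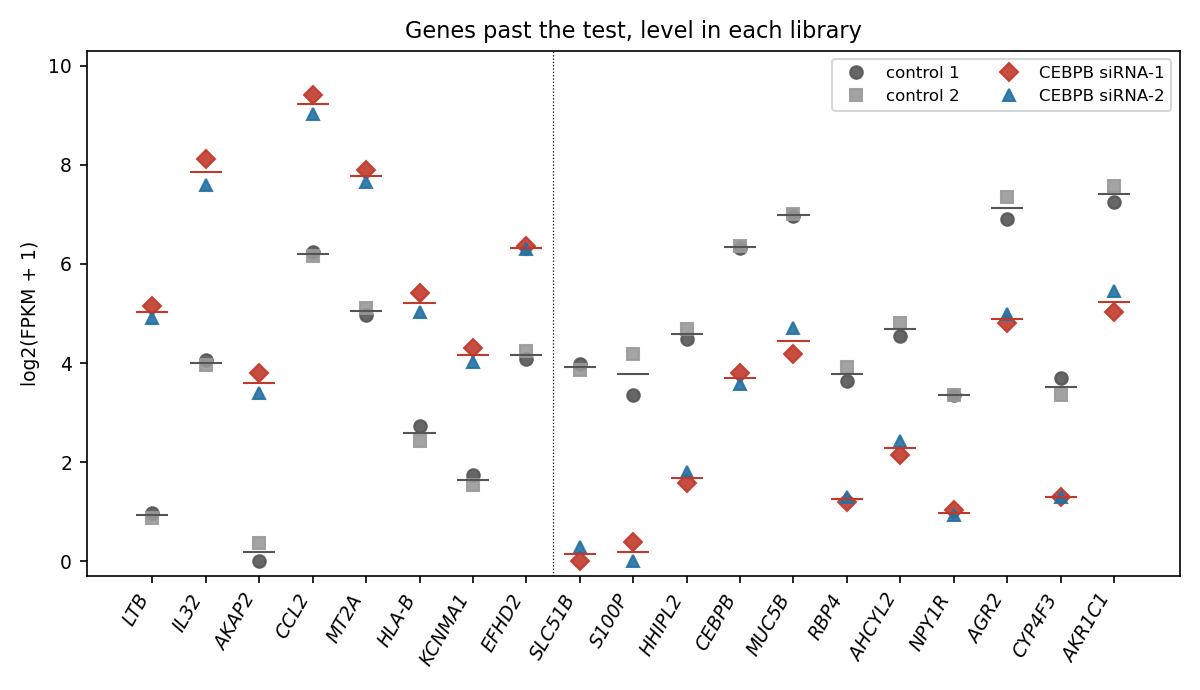
Level of each named gene in the 4 libraries, as log2(FPKM + 1). Points are single libraries and short lines are group means (n = 2), with genes that rose left of the dotted line and genes that fell right of it; for every gene shown, both siRNA libraries lie beyond both controls.

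Of 19 NRF2 glutathione and thioredoxin genes, 0 rose and 2 fell in limma over all genes, 9 fell when adjusted over the list alone, and 4 fell in the authors' deposited table. GPX2, a glutathione peroxidase, fell from 245 and 277 FPKM to 79.3 and 86.0, a log2 change of -1.64 ± 0.16. HMOX1, heme oxygenase 1, fell from 74.1 and 79.4 FPKM to 23.0 and 26.9 (log2 change -1.59 ± 0.17). The authors' table adds GLRX (-1.76) and OSGIN1 (-1.57). The list's median log2 change was -0.54 (camera adjusted p = 1.7e-08; adjusted p = 0.31 with an estimated correlation). NFE2L2, which encodes NRF2, was at 37.9 and 35.6 FPKM in the controls and at 28.2 and 26.6 in the siRNA libraries, and did not pass in either table. SLC7A11 (log2 change -0.12) and TXNRD1 (-0.18), both known NRF2 targets, did not pass either.

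Of 29 tested aldo-keto reductase and drug metabolism genes, 2 fell in limma, 7 when adjusted over the list alone and 8 in the authors' deposited table, with 0 higher in each. The authors' table gives log2 changes of -2.14 for AKR1C2, -1.16 for AKR1C3, -1.25 for MGST1 and -1.03 for ALDH3A1. The AKR1C genes are close paralogs that share reads, so their single levels are uncertain; their summed FPKM was 0.250 of the control mean with siRNA-1 and 0.356 with siRNA-2. The list's median was -0.47 (camera adjusted p = 8.4e-08; adjusted p = 0.31 with an estimated correlation). Of 8 NADPH and pentose phosphate genes, none fell in limma, 3 fell when adjusted over the list alone, and PGD fell in the authors' table (-0.94, from 859 and 981 FPKM to 452 and 476). Their median was -0.37 (camera adjusted p = 0.00024; adjusted p = 0.31 with an estimated correlation).

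Acute phase and complement genes had the lowest median of the lists tested, at -1.48 over 12 members (camera adjusted p = 3.5e-11; adjusted p = 0.31 with an estimated correlation). FGG, the fibrinogen gamma chain, fell in limma from 28.6 and 30.0 FPKM to 7.16 and 6.57 (log2 change -1.95 ± 0.17). In the list alone 11 fell, and 7 fell in the authors' deposited table, among them FGA (-2.46), FGB (-2.03), the copper carrier CP (-2.84) and LCN2 (-1.36). Complement C3 was at 62.0 and 74.3 FPKM in the controls, 12.4 with siRNA-1 and 45.3 with siRNA-2, and did not pass over all genes or in the authors' table. Among 8 hepatic and gastrointestinal lineage genes, 0 passed in limma, 4 fell in the list alone and 4 in the authors' table, namely FGB, also an acute phase gene, the transcription factor HNF4A (-1.38), the plasma glycoprotein APOH (-1.64) and CPS1 (-1.25). Their median was -0.74 (camera adjusted p = 0.0034; adjusted p = 0.31 with an estimated correlation, and 0.0698 with the preset one without siRNA-2), -0.47 without siRNA-1 and -0.19 with no filter. Of 6 alveolar and airway genes, MUC5B fell in limma, and 1 rose and 3 fell in the list alone. In the authors' table FOXA1 (-1.27) and MUC5AC (-0.89) also fell, while the lipid transporter ABCA3 rose (0.79). The median was -0.68 (camera adjusted p = 0.0223; adjusted p = 0.36 with an estimated correlation, 0.0574 without control 2, 0.0809 without siRNA-2, 0.0511 in the 3-group fit and 0.178 with no filter, where the median was -0.048).

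Of 16 cytokine and chemokine genes, 2 rose in limma (IL32 and CCL2), 6 rose and 2 fell in the list alone, and 6 rose and 1 fell in the authors' deposited table. That table gives log2 changes of 3.86 for IL11 and 1.74 for IL8, and -3.93 for CSF3, which was listed at 0 with siRNA-1. CSF2 was listed at 0 in both controls and was at 11.6 and 5.33 FPKM in the siRNA libraries. The list's median was 0.73, or 0.47 with no filter (camera adjusted p = 0.00084; adjusted p = 0.31 with an estimated correlation). Of 23 mesenchymal and extracellular matrix genes, 0 passed in limma, 12 rose and 1 fell in the list alone, and 11 rose and 1 fell in the authors' table. COL5A1 went from 0.394 and 0.526 FPKM to 7.50 and 4.45, and the authors' table gives 1.82 for CDH2, 1.70 for LOXL2, 1.57 for COL4A2 and -0.96 for fibronectin, FN1. The list's median was 1.0 (camera adjusted p = 8.4e-08; adjusted p = 0.36 with an estimated correlation). Per library it was 1.48 with siRNA-1 and 0.67 with siRNA-2.

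Of 20 p53 targets, 0 passed in limma and DDB2 rose in the list alone. In the authors' deposited table, DDB2 (0.99) and CDKN1A (1.15) rose and GDF15 (-1.45) fell. Their median was 0.61 (camera adjusted p = 1.8e-05; adjusted p = 0.31 with an estimated correlation). Of 15 apoptosis and BCL2 family genes, 0 passed in limma, and BCL2A1 rose in the list alone and in the authors' table (from 2.72 and 1.04 FPKM to 37.0 and 17.0). The median was 0.32 (camera adjusted p = 0.0064; adjusted p = 0.36 with an estimated correlation, 0.0612 without siRNA-2), and 0.18 without control 2. The median of 24 cholesterol synthesis genes was -0.26 (camera adjusted p = 0.0020; adjusted p = 0.55 with an estimated correlation, 0.934 without siRNA-2); it was -0.50 without siRNA-1, -0.060 without siRNA-2 and -0.17 without control 1. None of the 13 mitochondrially encoded genes passed in any of the 3 counts (MT-CO2 had the smallest p, -0.42), and their median was -0.16 (camera adjusted p = 0.0223; adjusted p = 0.65 with an estimated correlation). It was -0.27 without siRNA-1 or without control 1, and -0.016 without siRNA-2. The call was lost without control 2 (0.323), without siRNA-2 (0.813), with median-of-ratios (0.0712) or upper-quartile scaling (0.0520) and with no filter (0.148). By fry, of the 12 lists past camera only the NRF2, aldo-keto reductase and cytokine lists passed.

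**Figure D2:**
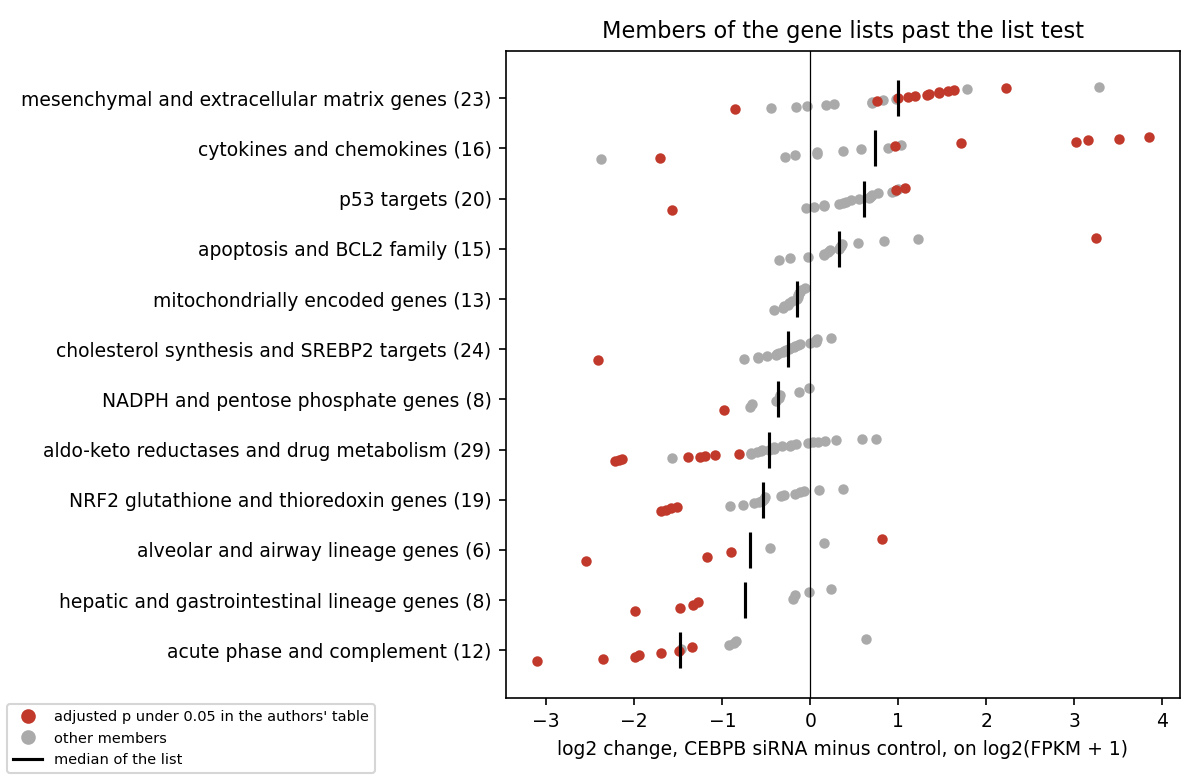
Log2 change of every tested member of the 12 lists past the camera threshold, CEBPB siRNA minus control on the log2(FPKM + 1) scale, with the number of members in parentheses. Each point is a gene and the black bar is the list's median, from -1.48 for acute phase and complement genes to 1.0 for mesenchymal and matrix genes.

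The other 16 lists with enough members did not pass camera. In the C/EBP family (6 members, adjusted p = 0.107) only CEBPB was called, and CEBPA (log2 change -0.52), CEBPD (0.13) and CEBPG (0.03) did not pass. Of 16 interferon-stimulated genes 0 passed in limma, in the list alone or in the authors' deposited table, with a median of 0.40 (adjusted p = 0.183); USP18 had the smallest p (-0.71). Among the 8 CNC and small MAF factors (adjusted p = 0.472), NFE2L3 rose in the list alone and in the authors' table (1.13). Of 10 NOTCH pathway genes (adjusted p = 0.199), 1 rose and 3 fell in the list alone. NOTCH3 (-2.13) and JAG1 (-0.86) fell and MAML2 (2.18) rose in the authors' table. Of 18 TGF-beta and activin genes (adjusted p = 0.698), 3 rose and 5 fell in the list alone. The authors' table has ID1 (-2.25), ID3 (-1.56), ID2 (-1.05) and BMP4 (-1.51), all in BMP signalling, lower, and LTBP2 (1.58) higher. Of 11 epithelial genes (adjusted p = 0.550), 4 rose and 4 fell in the list alone, and TJP3 (-2.29), KRT18 (-1.21) and CLDN2 (-1.15) fell in the authors' table. No gene rose or fell in any of the 3 counts for S phase (22 members, adjusted p = 0.156), G2 and M phase (26, 0.441) or histone genes (5, 0.856). The smallest p in these were those of RRM2 (-1.18), PLK1 (-0.52) and HIST2H2AC (-0.26). The median and mean differed in sign for the TGF-beta list (0.15 and -0.11), the histone list (0.05 and -0.03) and the immediate early list (-0.01 and 0.27); camera took the sign of the mean in the last 2 and of the median in the first.

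For the remaining lists the authors' deposited table calls at most 2 members each. In it ABCC6 (-1.87) fell among 9 ABC transporters (adjusted p = 0.107), where ABCC3 had the smallest limma p (-0.63, not past). CTH (-1.74) fell beside CEBPB itself among 25 ATF4 and amino acid response genes (0.729), and XBP1 (-0.94) among 16 unfolded protein response genes (0.107). PLIN2 (-0.92) and SCD (-0.83) fell among 19 fatty acid and lipid storage genes (0.472), and DUSP1 (1.09) rose among 18 immediate early genes (0.472). PFKFB4 (2.47) rose and CA12 (-0.68) fell among 21 hypoxia and glycolysis genes (0.826), and B2M (0.83) rose among 14 RNA interference and reference genes (0.123). PPIA, a common reference gene with the smallest limma p of that list, had a log2 change of 0.69 here and 0.26 in the authors' table, past the threshold in neither. In limma 0 of these passed apart from CEBPB; in the lists alone 2 fell in the ATF4 list, 2 fell in the lipid list and DUSP1 rose. Of markers of other cell types, 3 of 18 leukocyte, endothelial and erythroid genes and 1 of 11 fibroblast genes reached 1 FPKM, too few to test. CD14 was at 3.03 and 3.53 FPKM in the controls and at 0.862 and 2.0 in the siRNA libraries, and ACTA2 at 4.71 and 3.36 against 9.54 and 9.48.

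The 2 siRNAs target the same gene, so their changes were compared across genes. With siRNA-1 set against control 1 and siRNA-2 against control 2, log2 changes of the 14068 genes correlated at 0.440 (Spearman 0.345), and 59.2% had the same sign. With the controls crossed, the correlation was 0.376. Against both shared controls it was 0.557, where simulated unchanged groups gave 0.334; the covariance was 0.163 against 0.036 simulated, a difference of 0.127. The siRNA-1 library lay further from the controls: 1446 genes differed from the control mean by over 1 on the log2 scale, against 572 for siRNA-2 and 235 between the controls.

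**Figure D3:**
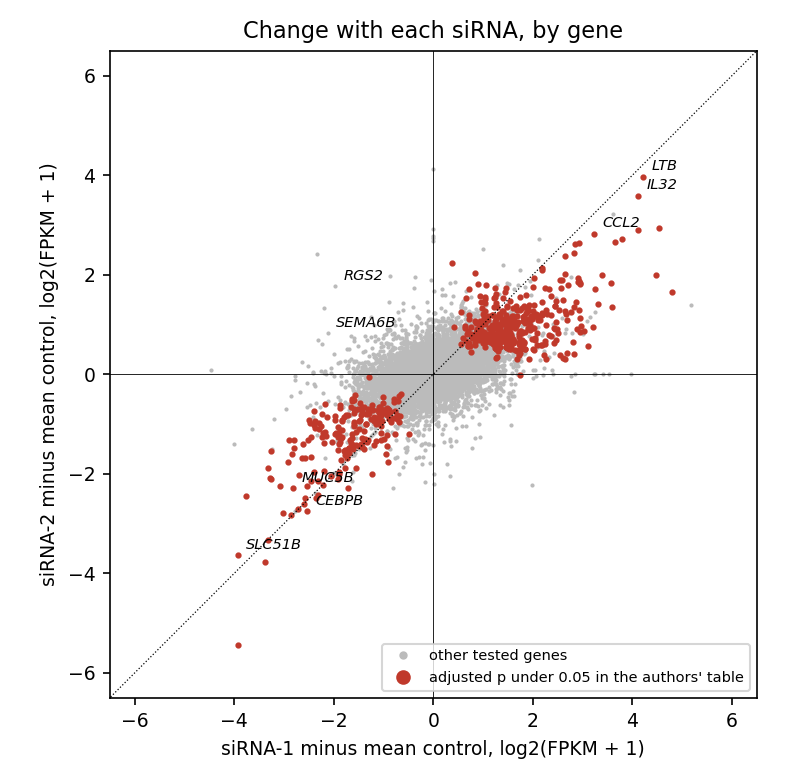
Log2 change of each of the 14068 tested genes with siRNA-1 (x) and siRNA-2 (y) against the mean of both controls, on the log2(FPKM + 1) scale. Red points are the 568 tested genes past 0.05 in the authors' deposited table and the dotted line marks equal change; 1446 genes lie beyond 1 with siRNA-1 and 572 with siRNA-2.

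Between the siRNAs, 16 genes were higher and 46 lower with siRNA-1 in the 3-group limma fit. RGS2, a regulator of G protein signalling, was at 9.28 and 8.31 FPKM in the controls, 1.5 with siRNA-1 and 32.2 with siRNA-2. The semaphorin SEMA6B was at 12.1 and 9.78 FPKM in the controls, 1.73 with siRNA-1 and 20.1 with siRNA-2. AL441883.1 and RP11-275N1.1 were listed at 0 with siRNA-1 and at 22.2 and 6.99 FPKM with siRNA-2, and AC104534.3 was listed at 0 in all libraries but siRNA-2 (16.5). The 5 largest differences upward, RPL36A-HNRNPH2, APOC1P1, TM9SF1 (ENSG00000254692.1), TMSB4XP6 and AC008964.1, were at 8.37 to 14.8 FPKM with siRNA-1 and listed at 0 in the other 3 libraries. RPL36A-HNRNPH2 is a readthrough locus, and APOC1P1 and TMSB4XP6 are pseudogenes, so their reads may be shared with other genes. The authors' deposited table has a mean normalized count of 2.28 for APOC1P1 and of 0 for the other 4, AL441883.1 and AC104534.3, so these levels are uncertain. Chosen after their values were seen, the proteoglycan SDC1, whose 3' UTR carries the word GCCCGT (58.5 and 59.7 FPKM in the controls, 8.64 with siRNA-1, 70.1 with siRNA-2) and TGM2 (137, 159, 20.7 and 145) were lower with siRNA-1, and the receptor AXL (14.9, 15.0, 354 and 62.8) was higher. All the named differences had an adjusted p of 0.0404. Each siRNA is 1 library and the spread comes from the controls alone (1 residual degree of freedom), so these are differences between libraries that need not be due to the siRNAs. The counts depend on the settings: with upper-quartile scaling 0 genes passed, with a pseudocount of 0.1 only 1 lower gene passed, with median-of-ratios scaling 191 higher and 173 lower, and with no filter 909 higher and 1006 lower.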

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

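The test on 7-mers in 3' UTRs was written before its result was seen; the other tests here were chosen afterwards, those on 6- and 8-base words included.

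Genes that differed between the siRNAs under the same contrast with the controls numbered 16 higher and 46 lower with siRNA-1, by the 3-group limma test of the difference itself. Each siRNA is 1 library and the spread comes from the 2 controls alone, and the counts ran from 0 and 0 to 909 and 1006 over the settings, so these are differences between libraries that may not recur (a pseudocount of 0.1 left 1). On the log2(FPKM + 1) scale the differences, siRNA-1 minus siRNA-2, were -3.73 for RGS2, -2.95 for SEMA6B, -4.54 for AL441883.1, -4.13 for AC104534.3 and -2.998 for RP11-275N1.1. They were 3.98 for RPL36A-HNRNPH2, 3.52 for APOC1P1, 3.42 for TM9SF1, 3.25 for TMSB4XP6 and 3.23 for AC008964.1. The last 5 genes and AC104534.3 were listed at 0 in the other 3 libraries, so their differences depend on the pseudocount and are not folds.

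The siRNA-1 library moved more genes than siRNA-2, with 1446 against 572 beyond 1 on the log2 scale. Lower depth is argued against, since the relative depth with siRNA-1 was 1.02 and the lowest of the 4 libraries was 0.967. A larger response of the same kind may account for part of it. Against single controls, 1533 or 1588 genes lay beyond 1 with siRNA-1. At least 76.8% of them moved the same way with siRNA-2 against the other control, where 59.2% and 56.9% of all tested genes did. The median size was 0.27 to 0.31 of that with siRNA-1, a ratio lowered by choosing genes for a large siRNA-1 change. CEBPB itself was no lower with siRNA-1 (12.9 FPKM) than with siRNA-2 (10.97 FPKM), so its level gives no sign of a larger response. The 48 genes that differed between the siRNAs and were above 0 in all libraries decide nothing. Choosing them by that difference favours opposite changes (35.4% moved the same way). Seed matches outside CEBPB were tested in 3' UTRs. The leading 7-mer, TGCCCGT, had a z of -7.67. The test written beforehand required a z below the lowest between the controls (-4.21), which was met. With the arbitrary sign of that difference turned, the z lay within its range (-4.21 to 7.94). The test also required the 7-mer on the mRNA strand of the CEBPB transcript, but it is on neither strand, so the test failed. Of the 10 leading 7-mers, 6 contain the 6-base core GCCCGT and 4 of these are in that transcript, as 9.3% of tested 7-mers are. These words overlap and are not independent. Since the core is in that transcript, some 7-mers that hold it must be there as well. The 9.3% is thus no chance rate for them, and their presence is no evidence of a seed. The core was found there as 28.2% of tested 6-mers are, or 45.5% on either strand. It had a z of -10.38 between the siRNAs, -8.78 with siRNA-1 against the controls, -0.66 with siRNA-2 and 1.19 between the controls (all 6-mers there -4.09 to 6.15). A seed of siRNA-1 thus stays only a candidate explanation for part of the difference, with a word chosen in the same genes. The word's 792 carriers shifted by -0.21. Of the 36 genes lower with siRNA-1 that have a 3' UTR and a mean of at least 5 FPKM, 11 carry it (0 of 10 higher and 9.3% of other genes do). The leading 8-mer, AAGCCCGT (z -7.03, between the controls -4.61 to 6.33), is on the opposite strand of the CEBPB transcript alone and ranked 5 against the controls. With siRNA-2 against the controls, where siRNA-1 plays no part, the highest z was 8.49 for 6-mers, 9.42 for 7-mers and 7.33 for 8-mers. Sizes like those of the leading 7-mer and 8-mer thus arose without siRNA-1. Indirect effects, library variation and the siRNA sequences, not used here, stay open.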

How the results depend on the processing

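The scalings, the filters other than none, the minimum fold, the authors' DESeq2 results and camera on their Wald statistics were chosen after seeing the data; the rest was planned. The planned edgeR, DESeq2 and voom fits and count-based scalings were not run because the table holds FPKM. The between-siRNA fit gave no value without each library in turn, since leaving out a control leaves no residual degrees of freedom and leaving out an siRNA removes an arm. No result past the threshold in either setting reversed its direction; 5 lists past it in neither changed camera direction, 9 times in all. Their medians without each library ran from -0.148 to 0.167 for ATF4, -0.81 to -0.152 for epithelial, 0.0350 to 0.189 for TGF-beta, -0.0376 to 0.167 for hypoxia and -0.093 to 0.090 for histone genes; TGF-beta was also turned by the Wald statistics (median 0.211). The 9 higher and 24 lower genes became 0 and 0 with no filter. There 27320 genes in place of 14068 were tested, and the spread was refitted over them. The number of tests alone does not account for the loss. The limma adjusted p of CEBPB went from 0.0167 to 0.262 at the same log2 change, a larger rise than that in the number of tests. The counts were 538 and 433 in the 3-group fit, where the controls alone set the spread. They were 5 and 5 for a fold of at least 1.5, and 398 and 209 in the authors' results. Leaving out 1 library gave 0 to 870 higher and 0 to 894 lower genes, with 3 libraries left and the lone one assumed to vary like the others. All 33 genes kept their sign with each library left out, which was fixed in advance because both siRNA libraries of each gene lie beyond both controls. Neither scaling moved the median log2 change of all genes by over 0.02. With a replicate block the counts were 11 and 14, with 20 of the genes shared; the numbers are not shown to pair the libraries (2 pairs, correlation of same-numbered deviations 0.075). CEBPB stayed between -2.75 and -2.54 without each library and at -2.65 with no filter, where its adjusted p was 0.262; over the alternatives the adjusted p ran from 8.5e-24 to 0.461. The 4 higher and 8 lower lists became 0 and 0 with an estimated correlation and 1 and 2 by fry, and ran from 3 to 4 and 4 to 9 without each library. Between the siRNAs, the 16 higher and 46 lower genes became 0 and 1 with a pseudocount of 0.1, 909 and 1006 with no filter, 191 and 173 with median-of-ratios scaling, 0 and 0 with upper-quartile scaling, 8 and 36 with FPKM of at least 1 in 2 libraries, 480 and 813 with a mean of at least 5, and 339 and 485 above 0 in all 4. Agreement of the siRNAs was 0.376 with the controls crossed and 0.551 at a mean of at least 10 FPKM, against 0.440. Of the values of named genes, 505 kept their direction and side of the threshold, 92 lost the call and 52 gained it; for single lists these numbers were 316, 33 and 6, and for genes named between the siRNAs 28, 21 and 0. The cause was not tested where none is given. Depth per library, on average 8341080 normalized counts in the authors' table, limits genes near 1 FPKM.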

Other observations

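The 4 gene lists in this part were written after the results were seen, and all tests here were chosen afterwards, so they describe these libraries and are not independent evidence. Of 17 class I antigen presentation genes, HLA-B rose in limma, 10 were higher and 0 lower in the authors' deposited table, and 15 had both siRNA libraries above both controls. HLA-C was at 27.7 and 25.3 FPKM in the controls and at 96.3 and 70.2 with the siRNAs, and the immunoproteasome subunit PSMB8 at 7.18 and 7.22 against 23.4 and 17.4. The median was 0.95 (camera p = 2.5e-15; p = 0.12 with an estimated correlation). Of 18 YAP and TEAD target genes, 0 passed in limma, 9 were higher and 0 lower in the authors' table, and the median was 0.92 (camera p = 4.7e-10; p = 0.082 with an estimated correlation). CYR61 was at 21.1 and 18.9 FPKM in the controls, 147 with siRNA-1 and 52.2 with siRNA-2, and AJUBA at 13.1 and 13.4 against 52.3 and 33.2.

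Of 14 secretory and mucosal defence genes, 5 fell in limma (MUC5B, AGR2, S100P, DEFB1 and PI3), and 9 were lower and 0 higher in the authors' deposited table. DEFB1, a defensin, was at 8.87 and 9.19 FPKM in the controls and listed at 0 in both siRNA libraries, as was the elastase inhibitor PI3 (5.38 and 4.80). SLPI, a related inhibitor, was at 38.1 and 47.4 FPKM in the controls, 1.88 with siRNA-1 and listed at 0 with siRNA-2. The median was -1.29 (camera p = 3.7e-17; p = 0.015 with an estimated correlation, or 0.059 adjusted over the 4 lists).

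The rise of HLA-B, IL32, LTB and CCL2 was weighed against 3 explanations. A shift of reads between HLA paralogs is argued against, since summed class I FPKM rose 3.21-fold with siRNA-1 and 2.36-fold with siRNA-2. A general interferon response to the siRNAs could not be decided. The interferon-stimulated list had a median of 0.40 ± 0.19 (SE by resampling) where the 4 genes rose by 2.64 or more. The 4 were chosen for large rises, so a list not chosen that way would fall short of them under either answer. Of the list's 16 members, 0 passed in limma. In both siRNA libraries, 7 of them lay above both controls and 4 below. NF-kappaB activity may contribute: 21 of its feedback genes had a median of 0.65 (camera p = 1.0e-07), but p was 0.17 with an estimated correlation, so the test leaves it open. A direct effect of CEBPB loss stays open and untested.

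The fall of NRF2 target genes was weighed against 2 explanations. Reads moved between AKR1C paralogs would leave their sum unchanged, but it was at 0.250 and 0.356 of the control mean. A fall of equal size in all NRF2 targets is argued against, since log2 changes of the 19 glutathione and thioredoxin genes had a standard deviation of 0.60, or 3.35 times their median standard error. A general loss of NRF2 activity with unequal responses is not excluded by this, since 14 of the 19 were lower and 1 higher in both siRNA libraries than in both controls. The hypothesis that part of the NRF2 programme depends on CEBPB stays open, and nothing here tests whether the dependence is direct.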
